A study of Mus musculus with 14 samples.

How the data were processed

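Stranded mRNA libraries of total RNA from spleen cells had been made with a TruSeq kit after Trizol and RNeasy extraction, per the labels' protocols. Reads had been aligned with STAR 2.3.0e to the mouse genome build GRCm38.p3, per the submitters' processing notes. The authors deposited raw read counts per gene, made with featureCounts 1.5.1 over the exons of the GENCODE vM3 annotation and summed per gene name, with neither a strand option nor a paired-end option on the command line, per the file headers. The counts were whole numbers with no normalisation or filter on genes, and 41053 gene rows were present in each of 2 tables, one for the GC B cells and one for the lymphoma B cells. How the GC B cells were purified, which part of Tet2 was deleted and how the lymphoma arose are not given in the sources used here. Coordinates are those in the files, on GRCm38. The reference annotation at hand was a later release and was used for no coordinate.

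Each library was mapped to its group and replicate by its title, and all 14 libraries were used. Total counts ranged from 27191862 to 30434184 in GC B cells and from 6691167 to 18598386 in lymphoma cells, of which 1525920 to 6775949 lay outside ribosomal RNA rows. Ribosomal RNA rows, and the ribosomal RNA share, mean throughout a hand-picked list of rows taken to hold reads of ribosomal RNA or other abundant structural RNA. Among its names are Yam1, Lars2, Rn7sk, Rpph1 and Rmrp, so the share is not one of annotated ribosomal RNA alone. Whether the reads of Yam1 and Lars2 come from ribosomal or structural RNA was not checked. A gene with 0 counts over a group was bounded with a floor of 3 counts over that group. No libraries were copies of each other, since differences between replicates exceeded counting error in every pair compared.

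The comparisons were KO against WT in the 4 and 3 GC B-cell libraries, shTet2 against control in the 2 and 5 lymphoma libraries, and the difference between these 2 effects in 1 model of all 4 groups. Each used edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group, robust quasi-likelihood fits and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. CPM are read counts scaled to a common library size with TMM factors, and log CPM used a prior count of 2. A set of 31 gene lists was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, where at least 3 members passed the filter, and again with a correlation estimated per list and with fry, a self-contained rotation test of whether the members move one way. Of 738 list members, 4 were matched through an older symbol and 3 were not matched. Calls shared by the 2 comparisons were tested with two-sided Fisher's exact tests. The comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, except where a choice is said to have been made later.

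The rule for named genes took, for each main comparison, Tet1, Tet2 and Tet3, then the 8 largest increases and 8 largest decreases among genes that passed the threshold, had a mean of at least 2 CPM and no overlap between groups. It left out predicted genes, clone-based symbols of a few kinds, mitochondrial genes, antigen receptor segments, Y-linked genes and Xist. It also took up to 3 members of each list that passed the threshold, or up to 2 with the smallest p where none did, of which the text may leave some out. For the difference between effects and for shared calls it took the 5 largest per direction. A few genes that met this rule are not reported here. Of 165 named genes, 56 overlap another gene and 42 overlap one on the other strand, by spans from first to last exon. These spans include introns, and exons were not compared. How far reads of such pairs can be mixed up in these counts is therefore not known.

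The tests were checked on simulated data with the real means and library sizes and 200 changed genes. For GC B cells (13397 genes tested) 77.3% of 2-fold and 99.0% of 4-fold changes were recovered, and 7.61% of calls were false. The lymphoma simulation (12573 genes) recovered 58% and 90.9% with 9.20% of calls false, and the simulation of the difference between effects (14948 genes) recovered 39.8% and 69.1% with 1.85% false. With no gene changed, 0, 2 and 1 genes were called. A mitosis list raised 1.5-fold was called in both simulated comparisons, also with an estimated correlation (adjusted p = 0.000125 and 0.00228), and 0 other lists were. Simulated genes varied independently, while the estimated correlation of this list in the real data was 0.52 in GC B cells and 0.57 in lymphoma cells. The simulation therefore does not show how often the test with an estimated correlation would call a real list.

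Alternatives were median-of-ratios and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter at 1 CPM, a minimum absolute log2 fold change of 1, removal of sex-linked, receptor segment and mitochondrial genes, 1 model of all libraries, the replicate number as a block, and leaving out each library in turn. Alternatives added after the data were seen were removal of ribosomal RNA rows, the mean level of 4 Y-linked genes or the ribosomal RNA share as a covariate, and leaving out control replicates 1 and 2 together. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.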

Results

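RNA abundance was measured by RNA-seq in 14 libraries of mouse spleen B cells on the C57BL/6 background, which fall into 4 groups. TET2 is an enzyme that oxidises methylated cytosine in DNA, and the series is about its loss. Germinal center (GC) B cells, the activated B cells that divide and mutate their antibody genes, were represented by 4 libraries labelled Tet2 knock-out (KO, replicates 2, 3, 4 and 5) and 3 wild-type libraries (WT, replicates 1, 3 and 4). Lymphoma B cells were represented by 5 control libraries (replicates 1 to 5) and 2 libraries labelled shTet2 (replicates 1 and 2), in which a short hairpin RNA was directed against Tet2. Total counts were 29487244 to 30330950 in the KO libraries and 27191862 to 30434184 in the WT libraries. They were 6691167 to 18598386 in the control lymphoma libraries and 9386084 to 14741588 in the shTet2 libraries. Ribosomal RNA rows, a hand-picked list that is not of annotated ribosomal RNA alone, took 0.370% to 1.32% of the counts in the GC B-cell libraries. They took 67.6% ± 8.36 (SD, n = 5) in the control lymphoma libraries and 49.5% ± 6.41 (SD, n = 2) in the shTet2 libraries. Among these rows, Yam1 alone took from 15.3% (shTet2 replicate 2) to 51.0% (control replicate 2) of the lymphoma counts. Outside these rows 1525920 to 6282880 counts were left in the control libraries and 5165550 to 6775949 in the shTet2 libraries. Values below are normalised read counts (CPM, scaled to a common library size), as mean ± SD, with n = 4 KO, 3 WT, 5 control and 2 shTet2 libraries. No label says that replicates came from separate animals, so the adjusted p-values measure the spread between these libraries.

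Tet2 itself (GRCm38 chromosome 3, 133463679 to 133544390) was measured first in every library. The KO libraries held 11.9, 14.6, 13.3 and 14.5 CPM in replicates 2 to 5, and the WT libraries held 13.4, 11.8 and 14.2 CPM in replicates 1, 3 and 4. The means of 13.5 ± 1.26 and 13.2 ± 1.22 CPM differed by less than the spread between replicates, with a log2 fold change of 0.04 (SE 0.13, adjusted p = 0.909), whose sign turned without KO replicate 3 (-0.00) or WT replicate 3 (-0.03). Counts over the whole gene can include exons outside a deleted part, so they do not check the KO label. The control lymphoma libraries held 68.0, 64.1, 58.1, 57.5 and 57.8 CPM in replicates 1 to 5, and the shTet2 libraries held 54.9 and 50.7 CPM. Both shTet2 libraries lay below all 5 controls, at 52.8 ± 2.99 against 61.1 ± 4.74 CPM, but the difference did not pass the test (log2 fold change -0.21, SE 0.10, adjusted p = 0.295). The group is therefore described by its label, shTet2, in every direction given for the lymphoma cells. Tet1 and Tet3, the other members of the enzyme family, did not pass the test in either comparison. Their log2 fold changes were -0.04 (SE 0.29) and 0.27 (SE 0.13) in the KO GC B cells, and -1.21 (SE 0.46) and -0.38 (SE 0.12) in the shTet2 lymphoma cells. The fit without shTet2 replicate 1, which leaves a lone sample in that group, called Tet3 lower at -0.63, and the sign of Tet1 in the GC B cells turned without KO replicate 2 (0.07), KO replicate 3 (0.02) or WT replicate 4 (0.00).

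The comparison of KO with WT GC B cells asks which genes change in normal GC B cells with the Tet2 KO, and in which direction. Tbx21, which encodes the transcription factor T-bet, fell in the KO cells to 9.94 ± 1.91 CPM from 71.8 ± 8.17 CPM in the WT cells (log2 fold change -2.85, SE 0.14, adjusted p = 1.73e-08). Cxcr3, a chemokine receptor gene whose transcription T-bet drives, fell to 5.94 ± 0.552 from 44.2 ± 5.66 CPM (-2.89, SE 0.12, adjusted p = 3.97e-09). Tox2, an HMG-box transcription factor gene, fell to 6.58 ± 2.19 from 49.5 ± 7.99 CPM (-2.91, SE 0.26, adjusted p = 0.000356). Memory and naive B-cell genes, MHC class I genes and myeloid marker genes held 12 of 24, 8 of 22 and 11 of 18 lower calls. Their calls as lists were lost with an estimated correlation (adjusted p = 0.132, 0.158 and 0.154), and mitosis and replication lists gave no call. Of 13600 genes tested, 883 passed the threshold, 261 higher and 622 lower, so that 70.4% of the calls were lower in the KO cells. With a change of at least 2-fold required as well, 73 genes were higher and 228 lower. Y-linked transcripts were higher in the same KO libraries, by 0.61 to 0.99 on the log2 scale. Xist, the RNA of the inactive X chromosome, stood at 359 ± 93.4 against 433 ± 52.3 CPM (-0.27, SE 0.20, adjusted p = 0.516), so each group held transcripts typical of both sexes. A fit with the Y-linked level as a covariate, chosen after the data were seen, called 4 genes higher and 0 lower with edgeR (566 genes at an unadjusted p under 0.05, 411 of them lower). DESeq2 called 37 genes, 21 of them lower, and limma-voom called 0. Mean log2 shifts of the Y-linked genes and Xist from the WT mean were 0.43 to 0.68 in KO and -0.15 to 0.15 in WT libraries. The Y-linked level and the group moved together, so the covariate fit cannot separate them. The count of higher calls was 154 without KO replicate 5 and 149 without WT replicate 3.

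The genes with the largest falls included Fam135a, from 24.3 ± 9.53 CPM in WT to 2.53 ± 0.600 CPM in KO cells (log2 fold change -3.26, SE 0.28), and Mcf2l, which encodes a guanine nucleotide exchange factor, from 12.2 ± 3.91 to 1.5 ± 0.452 CPM (-3.02, SE 0.27). Art3, of the ADP-ribosyltransferase family, fell from 4.96 ± 0.450 to 0.558 ± 0.209 CPM (-3.15, SE 0.27). Its span overlaps those of the chemokine genes Cxcl10 and Cxcl11 on the other strand. The counting used no strand option and exons were not compared, so whether reads of these genes were mixed up is not known. RP24-63G4.11 (-2.99, SE 0.25) and Ephb2, a receptor tyrosine kinase gene (-2.67, SE 0.30), completed the 8 falls. Among the genes that rose, Sva, known as seminal vesicle antigen, had 528 counts in the KO libraries (4.43 ± 1.47 CPM) and 0 in the WT libraries, at least 130-fold higher against a floor of 3 counts over the WT group (0.0340 CPM). Spp1, which encodes the secreted phosphoprotein osteopontin, rose to 3.48 ± 1.30 from 0.613 ± 0.222 CPM (2.48, SE 0.35, adjusted p = 0.000423). Fam83f rose to 9.20 ± 0.985 from 2.05 ± 0.637 CPM (2.17, SE 0.21), and Tmem176b rose to 5.15 ± 0.892 from 1.43 ± 0.0956 CPM (1.85, SE 0.22). Hfm1, a meiotic DNA helicase gene, rose by 1.84 (SE 0.26), and Lifr, the receptor gene for leukemia inhibitory factor, by 1.82 (SE 0.30). Cabp1, a calcium-binding protein gene, rose by 1.52 (SE 0.26), and Dnah1, an axonemal dynein heavy chain gene, by 1.51 (SE 0.29). All 16 of these genes kept their call in each of the 7 fits that left out 1 library. Floors cover counting error only.

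**Figure D1:**
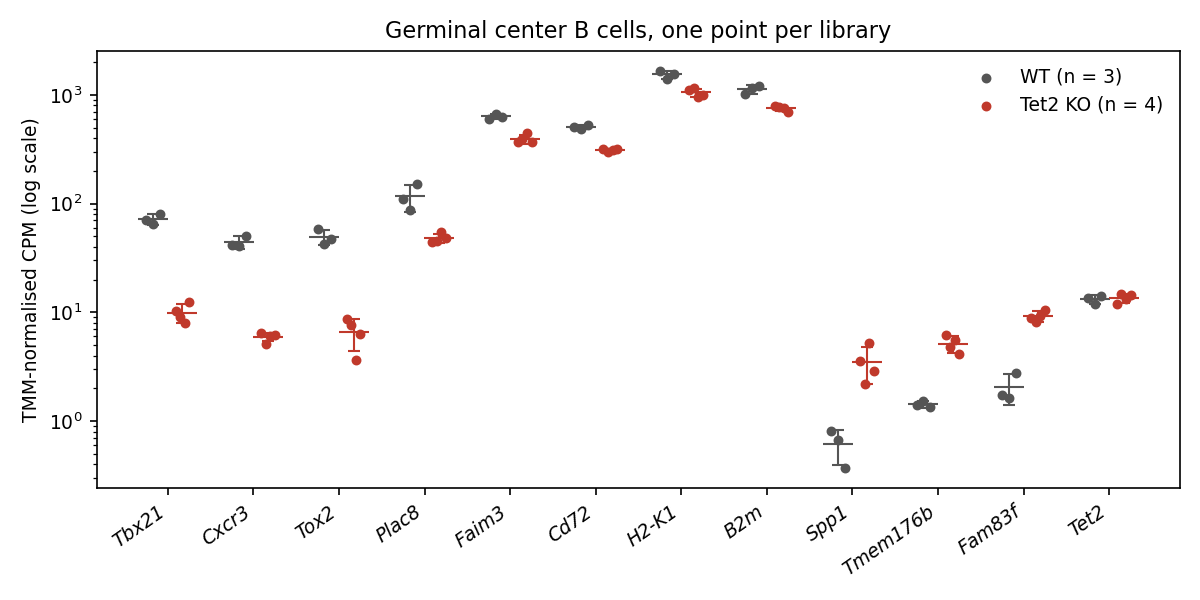
Normalised read counts in CPM (log axis) of 12 genes in the 4 KO and 3 WT GC B-cell libraries, with each point a library and bars showing the mean ± SD. Tbx21 stood at 9.94 CPM in KO and 71.8 CPM in WT cells and Fam83f at 9.20 and 2.05 CPM, while Tet2 stood at 13.5 and 13.2 CPM.

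Genes of memory and naive B cells gave 0 higher and 12 lower calls among 24 tested members (1 higher and 18 lower when adjusted over the list alone). The median log2 fold change was -0.43 (camera adjusted p = 6.22e-12, and adjusted p = 0.132 with an estimated correlation). Faim3, also known as the Fc receptor for IgM, fell to 393 ± 37.1 from 635 ± 35.5 CPM (-0.69, SE 0.09). Plac8 fell to 47.9 ± 4.51 from 117 ± 32.4 CPM (-1.28, SE 0.16), and Cd80, which encodes a T-cell costimulatory ligand, fell by 1.38 on the log2 scale (SE 0.18). MHC class I genes, which present peptides to CD8 T cells, gave 0 higher and 8 lower calls among 22 (0 and 13 adjusted over the list alone). The median was -0.23 (adjusted p = 5.53e-10, and adjusted p = 0.158 with an estimated correlation). B2m, the invariant light chain, fell to 752 ± 40.5 from 1128 ± 101 CPM (-0.58, SE 0.09), and the heavy-chain gene H2-K1 fell to 1053 ± 90.7 from 1541 ± 130 CPM (-0.55, SE 0.09). H2-Q7 changed by -1.03 (SE 0.13), and reads of these similar heavy-chain genes can be split between copies. B2m also overlaps Patl2 on the other strand. Light zone and activation genes gave 0 higher and 6 lower calls among 26 (2 and 10 adjusted over the list alone). The median was -0.10 (adjusted p = 0.0190, and adjusted p = 0.529 with an estimated correlation). Egr1, an immediate early transcription factor gene, changed by -0.63 (SE 0.10) and Ccr7, a chemokine receptor gene that guides lymphocytes to T-cell zones, by -0.89 (SE 0.15). This list lost its call without KO replicate 4 (adjusted p = 0.0510), WT replicate 1 (0.0509) or WT replicate 4 (0.0632), and with fry (0.0992). Marginal zone and B1 cell genes gave 0 higher and 6 lower calls among 18 (1 and 8 adjusted over the list alone). The median was -0.15 (adjusted p = 0.00386, and adjusted p = 0.222 with an estimated correlation). Bhlhe41, a basic helix-loop-helix repressor gene, fell to 8.19 ± 0.955 from 20.3 ± 2.41 CPM (-1.31, SE 0.13). Myeloid markers were lower in the same KO libraries, with a median of -1.01.

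Groups linked to B-cell signalling and related groups held single calls, and camera called none of them as a list. The GC programme list gave 0 higher and 3 lower calls among 21 (1 and 4 adjusted over the list alone). They were Cd38 (-0.97, SE 0.10), Basp1 (-0.60, SE 0.08) and the transcription cofactor gene Lmo2 (-0.45, SE 0.08). Cd38 is in fact low in mouse GC B cells, so its fall is not a fall of the GC programme. The list's median of 0.06 was positive while its mean of -0.05 and the camera direction were negative (adjusted p = 0.423). CD40 and NF-kB genes gave 0 higher and 4 lower calls among 26 (0 and 6 adjusted over the list alone). The median was -0.04 (adjusted p = 0.129). The members that fell included Nfkb2, which encodes the p100 subunit of NF-kB and overlaps Psd on the other strand (-0.50, SE 0.08). B-cell receptor signalling genes gave 0 higher and 3 lower calls among 31 (1 and 4 adjusted over the list alone). The median was -0.03 (adjusted p = 0.129). Cd72, an inhibitory co-receptor gene that overlaps Tesk1, fell to 310 ± 9.56 from 506 ± 22.2 CPM. Plasma cell genes gave 1 higher and 3 lower calls among 25 (2 and 4 adjusted over the list alone). The median was -0.13 (adjusted p = 0.0775), and Ly6c2 changed by -2.57 (SE 0.24). MHC class II genes gave 0 higher and 1 lower call among 18 (0 and 1 adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.0669), and fry called this list (adjusted p = 0.0146). Lymphoma tumour suppressor genes gave 0 higher and 4 lower calls among 30 (1 and 8 adjusted over the list alone). The median was -0.02 (adjusted p = 0.186), and Cd70, the ligand gene of CD27, was one of those that fell (-2.05, SE 0.40). Interferon response genes gave 1 higher and 1 lower call among 33 (1 and 1 adjusted over the list alone). The median was -0.10 (adjusted p = 0.947), and Oas1a, an antiviral oligoadenylate synthetase gene, changed by 0.96 (SE 0.19). BCL2 family and apoptosis genes gave 0 higher and 1 lower call among 22 (0 and 0 adjusted over the list alone). The median was 0.00 (adjusted p = 0.666). DNA methylation and demethylation genes gave 1 higher and 2 lower calls among 24 (1 and 3 adjusted over the list alone). The median was 0.03 (adjusted p = 0.729), and Gadd45g, of the growth arrest and DNA damage family, rose to 24.5 ± 4.08 from 12.9 ± 1.89 CPM (0.93, SE 0.15).

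Cell cycle and housekeeping groups held few calls or none in GC B cells. The edgeR test called 0 members, also when adjusted over the list alone, of the mitosis (25 tested, median 0.03, adjusted p = 0.285), replication (32, 0.07, 0.101), DNA repair (28, 0.06, 0.382), histone methyltransferase and acetyltransferase (30, 0.07, 0.129), oxidative phosphorylation (28, 0.02, 0.666), cytosolic ribosomal protein (36, 0.01, 0.461), mitochondrially encoded (10, 0.12, 0.316) and megakaryocyte and platelet (4, -0.03, 0.765) lists. At an unadjusted p under 0.05 these lists held 1, 3, 2, 4, 2, 2, 0 and 0 members in that order. DESeq2 called 1 histone enzyme gene and 0 members of the others, and limma-voom called 0. Glycolysis genes gave 1 higher and 1 lower call among 21 (3 and 1 adjusted over the list alone). The median was 0.16 (adjusted p = 0.0364, and adjusted p = 0.353 with an estimated correlation). The glycolysis call was lost without KO replicate 2 (adjusted p = 0.0798) or WT replicate 1 (0.159). MYC target genes gave 1 higher and 0 lower calls among 30 (1 and 0 adjusted over the list alone). The median was 0.06 (adjusted p = 0.129), and the transferrin receptor gene Tfrc changed by 0.46 (SE 0.09). Heat shock and immediate early genes gave 1 higher and 1 lower call among 22 (6 and 2 adjusted over the list alone). The median was 0.17 (adjusted p = 0.0652).

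Markers of other cell types moved apart. Myeloid markers gave 0 higher and 11 lower calls among 18 tested of 30 listed (0 and 15 adjusted over the list alone). The median was -1.01 (adjusted p = 8.78e-13, and adjusted p = 0.154 with an estimated correlation). Emr1, which encodes the macrophage protein F4/80, fell to 4.89 ± 0.502 from 12.4 ± 3.59 CPM (-1.34, SE 0.19). C1qa, a complement subunit gene, fell to 1.85 ± 0.307 from 4.61 ± 0.632 CPM (-1.32, SE 0.21), and Vcam1, an adhesion molecule gene, changed by -1.30 (SE 0.22). NK and plasmacytoid dendritic cell markers gave 0 higher and 3 lower calls among 10 (0 and 3 adjusted over the list alone). The median was -0.14 (adjusted p = 2.28e-05, and adjusted p = 0.132 with an estimated correlation). Tbx21 was one of them, beside Prf1, the perforin gene (-1.38, SE 0.32), whose call was lost without KO replicate 5 or WT replicate 3 (-1.59 to -1.18 over the 7 fits). Stromal and follicular dendritic markers gave 0 higher and 1 lower call among 5 (0 and 3 adjusted over the list alone). The median was -0.29 (adjusted p = 0.0310, and adjusted p = 0.296 with an estimated correlation). Leaving out KO replicate 2 ended this call (adjusted p = 0.0539). B-cell precursor markers gave 2 higher and 0 lower calls among 10 (4 and 0 adjusted over the list alone). The median was 0.21 (adjusted p = 0.0154, and adjusted p = 0.222 with an estimated correlation). Leaving out WT replicate 1 ended it (adjusted p = 0.159). T-cell markers gave 1 higher and 1 lower call among 12 (3 and 3 adjusted over the list alone). The median was 0.02 (adjusted p = 0.504). Thy1 rose to 2.31 ± 0.157 from 0.408 ± 0.231 CPM (2.51, SE 0.35). Erythroid markers gave 1 higher and 1 lower call among 9 (1 and 1 adjusted over the list alone). The median was -0.30 (adjusted p = 0.666). The Y-linked genes and Xist gave 4 higher and 0 lower calls among 5 (4 and 0 adjusted over the list alone). The median was 0.63 (adjusted p = 1.72e-06, and adjusted p = 0.132 with an estimated correlation). Ddx3y, an RNA helicase gene on the Y chromosome, rose to 56.3 ± 7.36 from 31.1 ± 5.15 CPM. In all, camera with its preset correlation called 10 of 31 lists, 3 up and 7 down. With an estimated correlation it called 0 (6 at an unadjusted p under 0.05, smallest adjusted p = 0.132). Fry called 10, with the MHC class II list in place of the light zone list.

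The comparison of shTet2 with control lymphoma B cells asks which genes differ when Tet2 is targeted in tumour cells. Mitosis genes were higher in the shTet2 cells, with 20 higher and 0 lower calls among 25 and a median log2 fold change of 1.71 (adjusted p = 0.101 with an estimated correlation). Cenpe, a kinetochore motor gene, rose to 32.8 ± 2.59 from 10.6 ± 1.81 CPM (1.62, SE 0.15, adjusted p = 0.000571). Cenpf, a kinetochore protein gene, rose to 28.1 ± 5.71 from 8.72 ± 2.03 CPM (1.67, SE 0.19), and the mitotic kinase gene Plk1 rose to 7.56 ± 1.92 from 1.89 ± 0.394 CPM (1.98, SE 0.25). Heat shock and immediate early genes gave 0 higher and 5 lower calls among 21 (adjusted p = 0.101 for the list with an estimated correlation). Zfp36, which encodes an mRNA decay factor, stood at 109 ± 11.7 against 239 ± 31.2 CPM (-1.13, SE 0.13), and Fos, a subunit gene of AP-1, at 160 ± 18.0 against 326 ± 49.1 CPM (-1.02, SE 0.15). Of 12797 genes tested, 330 passed the threshold, 235 higher and 95 lower in the shTet2 libraries, so 28.8% of the calls were lower. With at least a 2-fold change required as well, 148 were higher and 22 lower. The ribosomal RNA rows took a smaller share of the counts in the shTet2 libraries, 49.5% ± 6.41 against 67.6% ± 8.36. With this share as a covariate (chosen after the data were seen) edgeR called 0 genes (495 at an unadjusted p under 0.05), DESeq2 called 3 and limma-voom 0. The count of calls was 127, 143, 100 and 189 without control replicate 1, 2, 3 or 4, and 130 without shTet2 replicate 2. It was 2481 without shTet2 replicate 1, where the lone sample is assumed to vary like the other group, and 5 without control replicates 1 and 2 together, an alternative also chosen after the data were seen.

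Atp11a, which encodes a phospholipid flippase, rose to 13.8 ± 3.77 from 1.95 ± 0.831 CPM in the lymphoma cells (2.81, SE 0.29, adjusted p = 0.00212). Fscn1, an actin-bundling protein gene, rose to 6.64 ± 1.13 from 1.20 ± 0.648 CPM (2.35, SE 0.33), and Esco2, a cohesin acetyltransferase gene, rose to 7.73 ± 2.90 from 1.62 ± 0.468 CPM (2.21, SE 0.28). Ttk, a spindle checkpoint kinase gene, rose to 6.96 ± 3.14 from 1.29 ± 0.654 CPM (SE 0.37 on the log2 scale). Gatm, an enzyme gene of creatine synthesis, was higher too (2.23, SE 0.32), and Ssbp2, a single-stranded DNA binding protein gene, was lower (-1.32, SE 0.21). These 6 kept their call in each of the 7 fits that left out 1 library, and the other 8 named below did not. S1pr2, a sphingosine-1-phosphate receptor gene that confines B cells to germinal centers, rose to 24.1 ± 8.23 from 3.43 ± 1.98 CPM (2.73, SE 0.44, adjusted p = 0.0297). Its call was lost without control replicate 1, 2 or 3 or shTet2 replicate 2, with log2 fold changes of 2.33 to 3.03 over the 7 fits. Kif2c, a microtubule-depolymerising kinesin gene (2.37, SE 0.50), lost its call without control replicate 1, 2 or 4 or shTet2 replicate 2 (2.05 to 2.76 over the 7 fits), and Mcm10, a replication initiation gene (2.14, SE 0.44), without control replicate 1, 2, 3 or 4 or shTet2 replicate 2 (1.66 to 2.49). Atf3, a stress-induced transcription factor gene, fell to 0.786 ± 0.0686 from 5.31 ± 2.20 CPM (-2.69, SE 0.44), and Ifrd1 fell to 21.3 ± 2.46 from 63.4 ± 13.8 CPM (-1.56, SE 0.22), and in the fits that left out 1 library both lost the call without shTet2 replicate 2 alone (adjusted p = 0.106 and 0.235). Limma-voom did not call Atf3 or, among the plasma cell genes, Prdm1. Kalrn, a guanine nucleotide exchange factor gene (-1.94, SE 0.38), lost it without control replicate 1, 2 or 3 (-2.17 to -1.72), and Slc14a1, a urea transporter gene (-1.32, SE 0.26), without control replicate 1 or 3 or shTet2 replicate 2 (-1.54 to -1.12). Tmem184a (-1.55, SE 0.35) kept it only without shTet2 replicate 1 (-1.93 to -1.29).

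**Figure D2:**
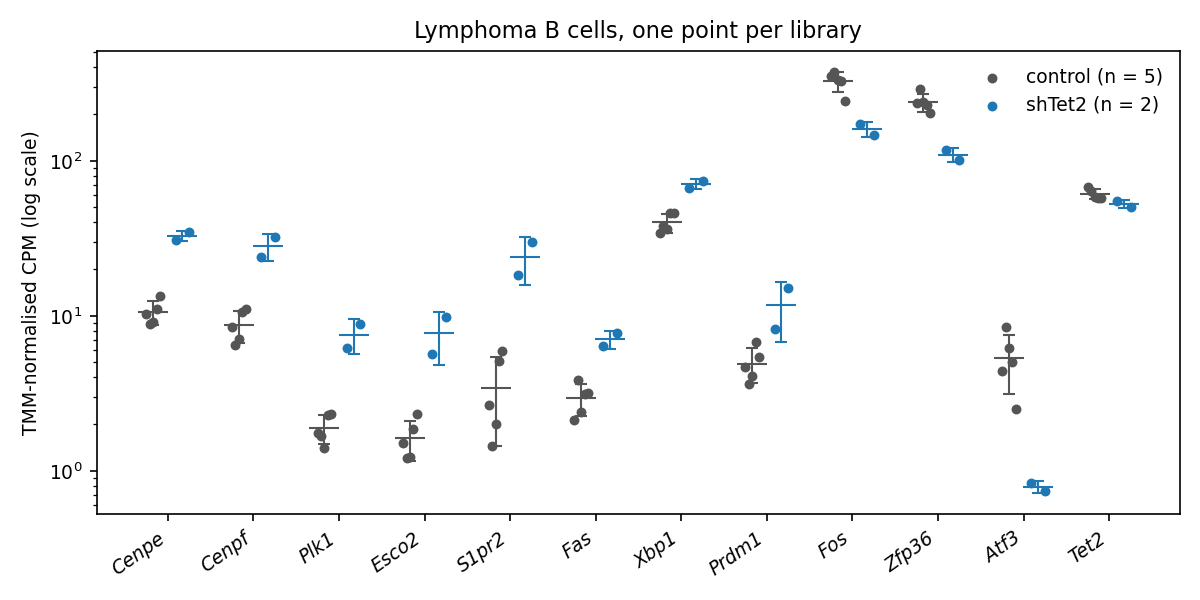
Normalised read counts in CPM (log axis) of 12 genes in the 2 shTet2 and 5 control lymphoma libraries, with each point a library and bars showing the mean ± SD. Cenpe stood at 32.8 CPM in shTet2 and 10.6 CPM in control cells and Zfp36 at 109 and 239 CPM, while Tet2 stood at 52.8 and 61.1 CPM.

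The mitosis list gave 22 higher and 1 lower call when adjusted over the list alone (camera adjusted p = 8.63e-49, and adjusted p = 0.101 with an estimated correlation). Its mean shift per library ranged from -0.47 to 0.41 in the controls and was 1.26 and 1.77 in the shTet2 libraries. Replication genes gave 10 higher and 0 lower calls among 32 (21 and 0 adjusted over the list alone). The median was 0.80 (adjusted p = 6.99e-20, and adjusted p = 0.120 with an estimated correlation). Pola1, the catalytic subunit gene of DNA polymerase alpha, rose to 30.0 ± 1.79 from 17.2 ± 1.56 CPM (0.82, SE 0.11). GC programme genes gave 4 higher and 0 lower calls among 21 (11 and 1 adjusted over the list alone). The median was 0.85 (adjusted p = 5.29e-07, and adjusted p = 0.101 with an estimated correlation). Fas, the death receptor gene, rose to 7.06 ± 0.915 from 2.94 ± 0.679 CPM (1.29, SE 0.23), a call lost without shTet2 replicate 2 (adjusted p = 0.0611). Plasma cell genes gave 5 higher and 0 lower calls among 23 (12 and 1 adjusted over the list alone). The median was 0.57 (adjusted p = 3.16e-07, and adjusted p = 0.360 with an estimated correlation). Xbp1, a transcription factor gene of the secretory programme, rose to 70.6 ± 5.22 from 40.0 ± 5.61 CPM (0.81, SE 0.13). Prdm1, which encodes the plasma cell regulator Blimp-1, rose by 1.21 (SE 0.26), but this call was lost without any 1 of control replicates 1, 2, 3 and 5 and shTet2 replicate 2 (0.71 to 1.58 over the 7 fits). DNA repair genes gave 4 higher and 0 lower calls among 28 (5 and 0 adjusted over the list alone). The median was 0.19 (adjusted p = 0.00103, and adjusted p = 0.275 with an estimated correlation). Fancd2, a Fanconi anemia gene, rose by 1.45 (SE 0.28), a call lost without control replicate 1, 2 or 3 or shTet2 replicate 2 (0.97 to 1.82 over the 7 fits). The share of ribosomal RNA counts was lower in the same shTet2 libraries.

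Heat shock and immediate early genes gave 0 higher and 5 lower calls among 21 lymphoma genes tested (0 and 13 adjusted over the list alone). The median was -0.77 (adjusted p = 3.23e-13, and adjusted p = 0.101 with an estimated correlation). Dusp1, a MAP kinase phosphatase gene, changed by -1.03 (SE 0.16) and, like Zfp36, kept its call in all 7 fits, while Fos lost it without shTet2 replicate 2 (adjusted p = 0.129). Mitochondrially encoded genes gave 0 higher and 5 lower calls among 7 (0 and 6 adjusted over the list alone). The median was -0.63 (adjusted p = 2.45e-08, and adjusted p = 0.275 with an estimated correlation). Interferon response genes gave 0 higher and 1 lower call among 33 (0 and 4 adjusted over the list alone). The median was -0.33 (adjusted p = 5.39e-07, and adjusted p = 0.360 with an estimated correlation). The call was lost without shTet2 replicate 1 (adjusted p = 0.423). The member that fell was Oasl2 (-0.98, SE 0.19), whose call was lost without control replicate 2 or 3 (-1.28 to -0.72 over the 7 fits). CD40 and NF-kB genes gave 0 higher and 1 lower call among 25 (0 and 1 adjusted over the list alone). The median was -0.16 (adjusted p = 0.00766, and adjusted p = 0.343 with an estimated correlation). Rel, which encodes the NF-kB subunit c-Rel, changed by -0.74 (SE 0.14) and lost its call without control replicate 1 or 3 or shTet2 replicate 2 (-1.03 to -0.51 over the 7 fits). Histone methyltransferase and acetyltransferase genes gave 0 higher and 1 lower call among 30 (4 and 7 adjusted over the list alone). The median was negative (adjusted p = 0.0154, and adjusted p = 0.360 with an estimated correlation), and the list's call was lost without shTet2 replicate 2 (adjusted p = 0.172). Kdm6b, in fact a histone demethylase gene, was the member called (-0.94, SE 0.17), and its call was lost without control replicate 2 (adjusted p = 0.0522).

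Metabolic lists held few single calls in the shTet2 lymphoma cells, and their calls as lists were lost with an estimated correlation (adjusted p = 0.360) and with fry (adjusted p = 0.0937 for oxidative phosphorylation, 0.104 for glycolysis and 0.105 for MYC targets). Oxidative phosphorylation genes gave 0 calls with edgeR among 28 (13 higher and 0 lower adjusted over the list alone, 17 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with limma-voom). The median was 0.39 (adjusted p = 4.22e-08, and adjusted p = 0.360 with an estimated correlation). Glycolysis genes gave 2 higher and 0 lower calls among 20 (4 and 0 adjusted over the list alone). The median was 0.22 (adjusted p = 0.00681, and adjusted p = 0.360 with an estimated correlation). MYC target genes gave 1 higher and 0 lower calls among 30 (3 and 0 adjusted over the list alone). The median was 0.25 (adjusted p = 0.00305, and adjusted p = 0.360 with an estimated correlation). Both lists lost the call without shTet2 replicate 2 (adjusted p = 0.149 and 0.436). B-cell precursor markers gave 0 calls among 11 (0 higher and 1 lower adjusted over the list alone, 4 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with limma-voom). The median was negative (adjusted p = 0.0318, and adjusted p = 0.360 with an estimated correlation). That call was lost without control replicate 1, 3, 4 or 5 or shTet2 replicate 2 (adjusted p = 0.0984, 0.0948, 0.127, 0.211 and 0.347).

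The remaining lists of the lymphoma comparison gave no camera call. Light zone genes gave 0 higher and 1 lower call among 26 (0 and 4 adjusted over the list alone, median -0.12, adjusted p = 0.117). B-cell receptor genes gave 0 and 2 among 31 (1 and 3 adjusted over the list alone, median -0.05, adjusted p = 0.217), and MHC class I genes 2 and 0 among 22 (3 and 0 adjusted over the list alone, adjusted p = 0.976). Apoptosis genes gave 1 and 0 among 21 (2 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.261), and DNA methylation genes 2 and 0 among 24 (6 and 1 adjusted over the list alone, median 0.12, adjusted p = 0.242). Tumour suppressor genes gave 3 and 0 among 27 (3 and 3 adjusted over the list alone, adjusted p = 0.241). The MHC class I median of -0.10 was negative while its mean of 0.01 and the camera direction were positive, and the tumour suppressor median of -0.21 and camera direction were negative while its mean was 0.07. With edgeR, 0 members passed among the 24 memory and naive B-cell genes (median -0.20 and direction down, mean 0.02, adjusted p = 0.0714), 18 MHC class II (-0.09, 0.265), 36 cytosolic ribosomal protein (0.04, 0.537), 19 T-cell (0.26, 0.481), 22 myeloid (0.07, 0.590), 5 erythroid (0.67, 0.225), 13 NK and plasmacytoid dendritic cell (0.20, 0.307), 4 stromal (-0.36, 0.242), 3 megakaryocyte (-0.05, 0.404) and 18 marginal zone genes (-0.06, 0.439). These lists held 10, 3, 6, 2, 3, 3, 2, 1, 1 and 2 members at an unadjusted p under 0.05 in that order. DESeq2 called 3, 0, 0, 0, 1, 1, 0, 0, 0 and 0, and limma-voom called 0. Adjusted over the list alone, 1 erythroid gene was higher and 1 stromal gene lower. Of the Y-linked genes and Xist, Xist was the 1 gene tested, at 998 ± 28.2 against 1333 ± 107 CPM (-0.42, SE 0.10, adjusted p = 0.0589), so this list had no camera test. DESeq2 and limma-voom called Xist. In all, camera called 14 of 30 lists, 8 up and 6 down. With an estimated correlation it called 0 (5 at an unadjusted p under 0.05, smallest adjusted p = 0.101). Fry called 8, among them the B-cell receptor list (adjusted p = 0.0231), which camera did not call. Besides the metabolic lists, fry did not call the plasma cell (adjusted p = 0.0937), interferon (0.144), histone enzyme (0.105) and B-cell precursor (0.105) lists.

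**Figure D3:**
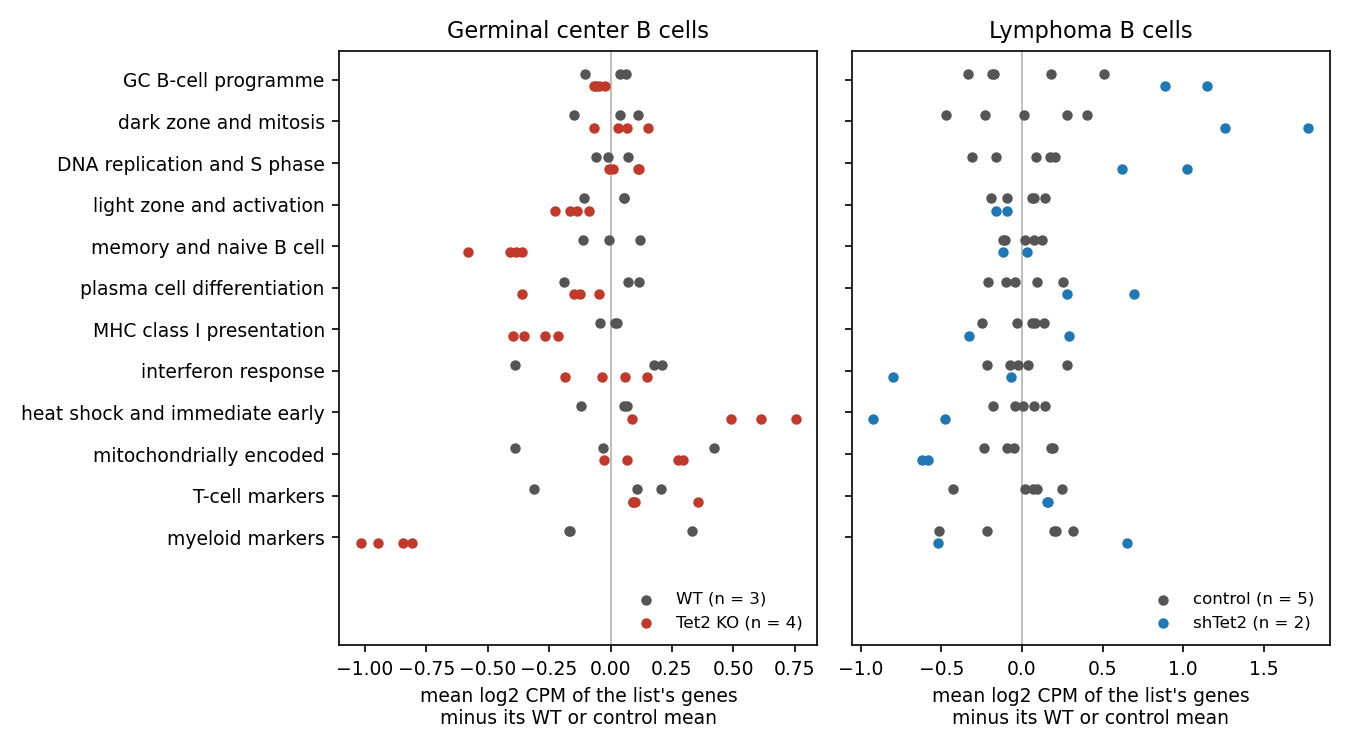
Mean log2 shift of 12 gene lists (vertical axis) from the mean of the WT or control libraries (horizontal axis) in each library of both comparisons, with each point a library. The mitosis list lay at 1.26 and 1.77 in the shTet2 libraries and between -0.47 and 0.41 in the control lymphoma libraries.

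Genes were then compared between the 2 cell contexts, which asks whether the KO and shTet2 groups differ from their controls in the same genes. Of 11679 genes tested in both, 28 were called in both comparisons, 15 in the same direction and 13 in opposite directions. Higher in both were 7 genes against 4.15 for independent lists (odds ratio 1.73, 95% interval 0.681 to 3.70, two-sided Fisher's exact p = 0.200, adjusted p = 0.400 over 4 tests), and lower in both were 8 against 4.21 (odds ratio 2.01, exact p = 0.0723, adjusted p = 0.289). Lower in KO and higher in shTet2 were 11 against 11.1 (exact p = 1), and higher in KO and lower in shTet2 were 2 against 1.57 (exact p = 0.672). The shared higher genes with the largest changes were Bcat1, a branched-chain amino acid transaminase gene (0.57 in KO and 1.97 in shTet2 cells), Esco2 (0.45 and 2.21), Atp11a (0.44 and 2.81), Gcat (0.42 and 2.0) and the Polycomb-associated gene Phf19 (0.41 and 1.19). The shared lower genes included the growth factor gene Tgfb3 (-0.78 and -1.01), Cdyl2 (-0.56 and -0.79), Pml, which encodes the organiser of PML nuclear bodies (-0.71 and -0.50), and Aff1 (-0.56 and -0.49). Across genes, which are not independent replicates, the log2 fold changes had Pearson's r of -0.04 and a Spearman correlation of 0.02, and 51.8% had the same sign. No library was shared by the 2 comparisons. Genes higher in both were 32 without shTet2 replicate 1 and 4 without shTet2 replicate 2, control replicate 3, WT replicate 1 or WT replicate 3. Genes lower in both were 61 without shTet2 replicate 1, 2 without shTet2 replicate 2, 1 without control replicate 1, 2 or 3, 3 without control replicate 4, WT replicate 1 or WT replicate 3, and 5 without KO replicate 4 or WT replicate 4. Pearson's r was 0.01 without WT replicate 3 and 0.06 without shTet2 replicate 2.

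**Figure D4:**
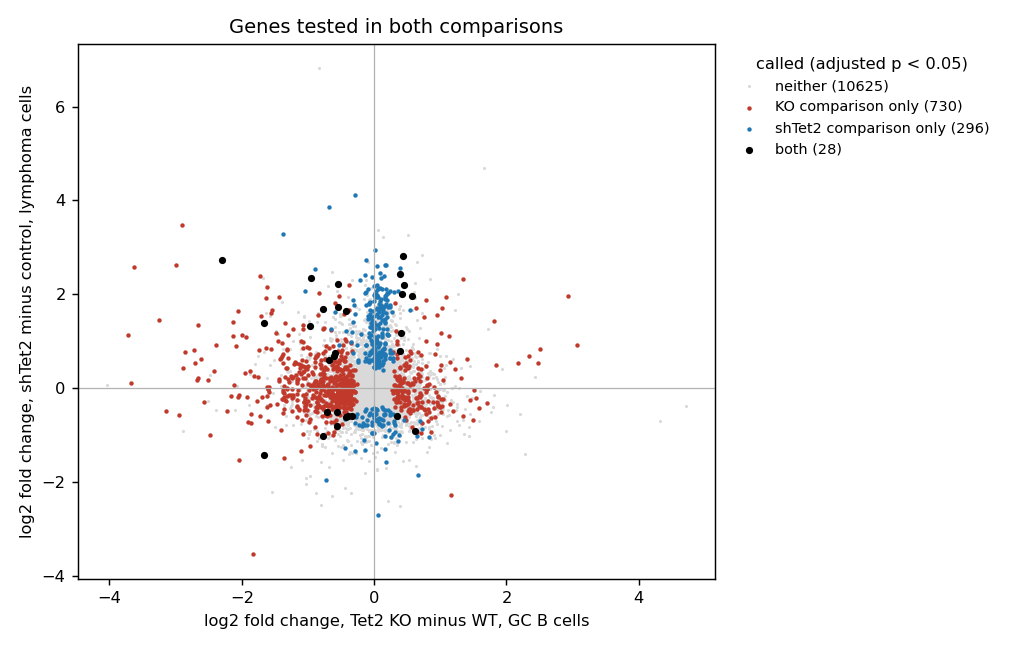
Log2 fold change in shTet2 against control lymphoma cells (vertical axis) against that in KO against WT GC B cells (horizontal axis), with each point 1 of 11679 genes, coloured by where it was called. The 28 genes called in both lie in all 4 quadrants, 15 with the same sign and 13 with opposite signs.

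A test of the difference between the 2 effects, KO minus WT less shTet2 minus control, called 771 of 15441 genes, 248 with a higher and 523 with a lower effect in GC B cells. The 2 comparisons differ in cell type, in how Tet2 was targeted and in the ribosomal RNA share. The test cannot tell these apart. Among the genes taken by the rule for named genes, Tox2 differed by -6.43 (SE 0.89, adjusted p = 0.00159). Its level normalised over all 14 libraries was 4.30 ± 1.44 CPM in KO, 31.3 ± 4.94 in WT, 0.223 ± 0.333 in control and 3.05 ± 2.97 in shTet2 libraries. Pipox, a pipecolic acid oxidase gene, differed by -5.05 (SE 0.76), from 20.8 ± 2.10 and 19.4 ± 0.872 CPM in KO and WT cells and 1.26 ± 0.742 CPM in shTet2 cells against 1 count in the controls. With so few control counts this is a fitted value and no bound, and with 1 library left out it ranged from -8.00 to -4.31. Fam135a (-4.70, SE 0.68), Mcf2l (-4.22, SE 0.61) and Chst1, a sulfotransferase gene (-4.00, SE 0.80), had negative differences too, as had RP24-63G4.11 (-5.59, SE 0.65). Among the positive differences, Cadm1, a cell adhesion molecule gene, stood at 1.74 ± 0.349 CPM in KO, 0.744 ± 0.105 in WT, 11.8 ± 6.83 in control and 2.57 ± 0.519 in shTet2 libraries (3.46, SE 0.62). Gcnt7 (4.34, SE 1.15), the clone-named gene at chromosome 9, 96027101 to 96040673 (3.35, SE 0.72), Myh7b, a myosin heavy chain gene (3.29, SE 0.93), and RP24-97J22.2 (3.13, SE 0.82) had positive differences too. They rested on 13, 30, 39 and 13 counts in KO and 0, 4, 5 and 1 counts in WT libraries, so these are fitted values and no bounds. Each of the 4 overlaps another gene. Among the shared higher genes, the effect was smaller in KO than in shTet2 cells for Esco2 (-1.72), Atp11a (-2.35), Gcat (-1.55) and Phf19 (-0.76). For Bcat1 the difference was -1.34 (adjusted p = 0.0952), and it did not pass for the 4 shared lower genes named. Mitosis genes (median difference -1.61, 0 higher and 21 lower among 25, 0 and 22 adjusted over the list alone), GC programme genes (-1.02, 1 and 9 among 21, 1 and 12 adjusted over the list alone) and heat shock and immediate early genes (1.06, 7 and 0 among 22, 14 and 0 adjusted over the list alone) each kept their call with an estimated correlation (adjusted p = 0.0470). The median of the mitosis genes was 0.03 in the KO and 1.71 in the shTet2 comparison. In the shTet2 libraries the share of ribosomal RNA counts was lower (49.5% against 67.6%), as was the median of mitochondrially encoded genes (-0.63). With that share as a covariate edgeR called 0 genes between shTet2 and control cells (495 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with limma-voom). Camera with its preset correlation called 15 lists, 5 up and 10 down, 3 of which were called with an estimated correlation, and fry called 6. The count of 771 was 455 without WT replicate 3, 499 without KO replicate 5, 510 without control replicate 3, 283 without shTet2 replicate 2 and 2001 without shTet2 replicate 1. Tox2, Pipox, Fam135a, Mcf2l, Cadm1 and the clone-named gene on chromosome 9 kept the call in all 14 such fits, Chst1 in 13 (lost without shTet2 replicate 2, at -2.87, and with limma-voom), RP24-97J22.2 in 9, Gcnt7 in 6 and Myh7b in 4. RP24-97J22.2 and Gcnt7 also lost the call with limma-voom, and Myh7b with upper-quartile scaling. With the replicate number as a block, RP24-97J22.2, Gcnt7, Myh7b, Pipox and the clone-named gene on chromosome 9 lost it.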

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

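The tests of Xist, of the T-cell markers, of the NK genes and Ighm and of the calls near Tet2, and the count of splits for lymphoma gene lists, were chosen only after the results were seen. Predictions for the tests with a covariate, for the further macrophage genes and for the other counts of splits were written before the values they measure. The covariates themselves were chosen after the data were seen.

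Among 92 groups of values checked for a library far from the rest of its group, 4 held one, and chance gives about 5%. RP24-97J22.2 stood at 13.1 CPM in control replicate 3, against 10.5 to 10.96 CPM in the other controls. Tox2 stood at 0.515 CPM in control replicate 5, against 0 to 0.117 CPM. The mean log2 shift of the CD40 and NF-kB list was -0.11 in control replicate 5, against 0.01 to 0.04 in the others. That of the oxidative phosphorylation list was 0.15 in control replicate 4, against -0.05 to -0.03.

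The KO effect in GC B cells and the shTet2 effect in lymphoma cells differed for 771 genes by a test of the difference itself. Among them were 29 of the genes named as Tet family members, as largest changes, for the difference or as shared calls. Genes named only as members of a gene list were left out of this count. The differences (GC B-cell minus lymphoma log2 fold change) were negative for Tox2 (-6.43), RP24-63G4.11 (-5.59), Pipox (-5.05), Fam135a (-4.70), Mcf2l (-4.22), Chst1 (-4.00), Ephb2 (-4.00), Tbx21 (-3.58), Cxcr3 (-3.31), Fscn1 (-3.26), S1pr2 (-2.81), Gatm (-2.72), Art3 (-2.63), Ttk (-2.45), Kif2c (-2.38), Atp11a (-2.35), Mcm10 (-2.04), Esco2 (-1.72), Gcat (-1.55) and Phf19 (-0.76). They were positive for Slc14a1 (1.20), Fam83f (1.67), Ifrd1 (1.78), Atf3 (2.79), RP24-97J22.2 (3.13), Myh7b (3.29), the clone-named gene at chromosome 9, 96027101 to 96040673 (3.35), Cadm1 (3.46) and Gcnt7 (4.34). Median differences of 3 lists passed with an estimated correlation (adjusted p = 0.0470), at -1.02 for the GC programme, -1.61 for mitosis and 1.06 for heat shock and immediate early genes. The share of ribosomal RNA counts was lower in the shTet2 than in the control libraries (49.5% against 67.6%), and the difference between effects was not fitted with that share as a covariate. Cell type, the way Tet2 was targeted and this share all differ between the 2 comparisons, so the test cannot tell them apart.

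In GC B cells 883 genes were called, and 1 of the 35 splits of the 7 libraries into groups of 4 and 3 gave as many, the real one, with 12 the highest of the others. A share of 1 in 35 is the smallest this test can give, so it argues against chance for this count but does not exclude it. Every other split mixes KO and WT libraries, so a difference between them widens the spread within its groups and lowers its calls. For the 10 gene lists called, 16 of the 35 splits gave as many and the highest other gave 17, so chance cannot be excluded for the number of lists. In lymphoma cells 330 genes were called, and 1 of the 21 splits into 2 and 5 gave as many, the real one, with 6 the highest of the others. For the 14 lymphoma lists, 6 of the 21 splits gave as many and the highest other gave 16, so chance cannot be excluded there.

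The pattern weighed first is the fall of Tbx21, Cxcr3, Cxcl10, Ighg2c and Ighg3 with the rise of Ighg1 in KO GC B cells, set out under the other observations. A different share of male cells is argued against by Xist, which changed by -0.27 (SE 0.20) where the smallest of the 5 falls, of Ighg3, was -1.10 (SE 0.22), and by Ighg1, whose rise of 2.93 exceeds that of any Y-linked gene (0.99 or less). The fit with the Y-linked level as a covariate, whose prediction was written before its values, did not decide alone. It went with that explanation for 2 of the 6 genes. The Y-linked level and the group moved together across the 7 libraries, so this fit cannot separate them. Ighg2c moved from -3.72 (SE 0.45) to -0.39 (SE 0.73), and Ighg3 from -1.10 (SE 0.22) to 0.26 (SE 0.75). Tbx21 (-2.85, SE 0.14, to -3.37, SE 0.55), Cxcr3 (-2.89, SE 0.12, to -2.99, SE 0.52), Cxcl10 (-2.52, SE 0.23, to -2.09, SE 0.93) and Ighg1 (2.93, SE 0.31, to 3.33, SE 1.23) lost their calls as standard errors rose. The median absolute change was 2.54 against 2.87 without the covariate, and 5 of 6 had the same sign. Another difference between the groups that goes with the Y-linked level stays open for Ighg2c and Ighg3. Fewer T cells are argued against by the T-cell markers, whose median was 0.019 over 12 tested genes (quartiles -0.44 and 0.73) with Cd3d at 0.39 CPM in WT cells. Fewer NK cells as the source of the Tbx21 and Cxcr3 falls are argued against by the 4 other NK genes tested, which stood at 1.87 CPM (SD 0.54, Prf1) or less in WT cells, where Cxcr3 lost 38.2 CPM and Tbx21 more. For the constant region genes they are argued against by Ighm, which changed by 0.015 (SE 0.11) where loss of cells without antibody transcripts would move all 4 alike. For Cxcl10 they stay open, since the 4 NK genes had a median of 0.11 (quartiles -0.32 and 0.22) at these low levels and Prf1 fell (-1.38, SE 0.32). A strain-derived segment within 10 Mb of Tet2 would hold 0 of the 6 genes of the pattern, which argues against a direct effect of such a segment on them. An indirect effect stays open. Whether such a segment exists was not decided, since 7 of 60 tested genes within 10 Mb of Tet2 were called, 11.7% against 6.47% elsewhere (two-sided Fisher's exact p = 0.110). The Tet2 KO itself, the difference the design names, stays open, and no further test of it was run.

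The fall of myeloid markers in KO GC B cells may come from fewer macrophages among the isolated cells or from a change within cells. A further list of 28 macrophage genes, 17 of which passed the filter, had a median of -0.40 (quartiles -1.25 and -0.14), between the -0.50 or lower written beforehand for fewer macrophages and the -0.25 or higher written against it. Slc40a1 (-1.44), Fcna (-1.36), Hpgd (-2.12) and Ctsb (-0.37) were called lower, and 0 members were called higher. Cd5l, at a low level, stood at 3.7 CPM in KO and 3.8 CPM in WT cells (-0.03, SE 0.20). Sirpa (0.26) and Creg1 (0.09) had positive changes that did not pass. The abundant Apoe stood at 544 CPM in KO and 646 CPM in WT cells (-0.25, adjusted p = 0.195). Genes at such a high level would hide a small share of macrophages, so the explanations cannot be told apart, and no purification step that would remove macrophages is named in the labels.

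The rise of mitosis genes in the shTet2 lymphoma cells might follow the lower share of ribosomal RNA counts, more dividing cells or fewer non-tumour cells. With the ribosomal RNA share as a covariate the median log2 fold change of the list was 1.04 (median SE 0.44) against 1.71 without it, and 0 of 25 members were called against 20, while camera called the list with its preset correlation (adjusted p = 3.62e-23) but not with an estimated correlation (adjusted p = 0.459), nor did fry (adjusted p = 0.398). The share and the group move together across 7 libraries, so these cannot be told apart. T-cell markers had a median of 0.26 over 19 genes (quartiles -0.21 and 0.48) and myeloid markers 0.07, where fewer such cells need falls. Stromal and follicular dendritic markers had a median of -0.36 over 4 genes, with 0 called. Members of the T-cell list went both ways, and fewer non-tumour cells stay open. Name stems differ between the shTet2 and control libraries, so a batch and the group cannot be told apart either.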

How the results depend on the processing

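The fits with a covariate, without ribosomal RNA rows and without control replicates 1 and 2 together were tests chosen only after the data were seen, and all other alternatives were planned. The cause of a change was not tested unless given here. Of the lists called in the KO and shTet2 comparisons, 152 values with 1 library left out stayed past the threshold in the same direction and 16 did not, and of those under other alternatives 80 did and 40 did not. Lists called for the difference between effects were not run under these alternatives, other than the estimated correlation and fry. Of named genes, 867 values with 1 library left out and 664 under other alternatives kept direction and side, 270 and 101 kept direction but missed the threshold, 3 reversed and 1 newly passed. DESeq2 kept 871 of the 883 KO calls and 315 of the 330 shTet2 calls. The replicate number as a block kept 451 and 2 of them, and 1 model of all libraries kept 535 and 310. Without WT replicate 3, 550 KO calls were kept, and without control replicate 3, 99 shTet2 calls. No scaling moved the median of all genes by over 0.1 or the share of lower calls by over 10 percentage points. Lymphoma depth limits genes of low level, since 1525920 counts outside ribosomal RNA rows were left in control replicate 2.

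In the KO comparison, requiring an absolute log2 fold change of 1 leaves fewer genes by construction (301, with 73 higher and 228 lower). DESeq2 called 443 higher, no filter gave 1365 with 504 higher, and 1 model of all 14 libraries gave 388 lower. The Y-linked covariate, which moved with the group, gave 4, with 4 higher and 0 lower (edgeR, 566 at an unadjusted p under 0.05). In the shTet2 comparison the fold minimum gave 170 (148 higher, 22 lower), DESeq2 593 (241 lower), no filter 782 (521 higher, 261 lower) and the model of all libraries 840 (662 higher, 178 lower). The ribosomal RNA covariate gave 0, with 0 higher and 0 lower (edgeR, 495 unadjusted, 3 with DESeq2), and leaving out control replicates 1 and 2 gave 5, with 5 higher and 0 lower (edgeR, 1717 unadjusted, 252 with DESeq2 and 1 with limma-voom). For the difference between effects, the fold minimum gave 479 with 94 higher and DESeq2 gave 1198 with 479 higher. Without a filter, shared calls were 23 higher and 29 lower. Camera with an estimated correlation called 0 lists in KO (6 unadjusted) and 0 in shTet2 cells (5 unadjusted), and fry called 8 lists in shTet2 cells.

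With 1 library left out, KO calls ranged from 607 to 944 (149 to 362 higher, 453 to 582 lower), shTet2 calls from 100 to 2481 (82 to 1303 higher, 18 to 1178 lower) and genes with a differing effect from 283 to 2001 (64 to 801 higher, 219 to 1200 lower). The upper ends for shTet2 calls and for differing effects came without shTet2 replicate 1, whose lone partner is assumed to vary like the controls. Called lists ranged from 8 to 14 in KO and 13 to 16 in shTet2 cells, Tet2 from -0.030 to 0.10 and from -0.27 to -0.15, Pearson's r from -0.088 to 0.062, the Spearman correlation from -0.058 to 0.10, and shared calls from 4 to 32 higher and 1 to 61 lower. Tet2 in KO cells turned sign without KO replicate 3 (-0.00) and WT replicate 3 (-0.030), and Tet1, which ranged from -0.20 to 0.070, without KO replicates 2 (0.070) and 3 (0.023) and WT replicate 4 (0.00).

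Replicate numbers 3 and 4 occur in KO and WT cells and 1 and 2 in shTet2 and control cells. Same-numbered libraries correlated at 0.03 and -0.02, and at -0.10 and -0.00, in their deviations from the group means. With 2 shTet2 libraries these deviations mirror each other by construction, and the labels do not say what a number marks. The correlations therefore neither show nor rule out that same-numbered libraries were paired. With the replicate number as a block, calls were 570 in KO cells (353 lower), 4 in shTet2 cells (3 higher, 1 lower) and 256 for the difference between effects (67 higher, 189 lower).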

Other observations

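The look at antibody constant region genes was chosen only after the results were seen. The covariate was also chosen after the data were seen, while the prediction for its test was written before the values it measures.

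Antibody constant region genes, which lie outside the rule for named genes, shifted between isotypes in the KO GC B cells. Ighg1, the IgG1 heavy chain constant region on chromosome 12, rose to 1141 ± 356 CPM (SD, n = 4) from 149 ± 26.7 CPM (SD, n = 3), 7.64-fold (log2 fold change 2.93, SE 0.31, edgeR adjusted p = 0.00344). Ighg2c, an isotype whose switching T-bet promotes, fell to 77 ± 30.7 from 1017 ± 444 CPM, 13.2-fold lower (-3.72, SE 0.45, adjusted p = 0.00964), and Ighg3 fell to 258 ± 61.3 from 556 ± 123 CPM (-1.10, SE 0.22, adjusted p = 0.0276). Ighg2b stood at 724 ± 155 and 913 ± 260 CPM (-0.33, adjusted p = 0.540), Igha at 5.29 ± 2.94 and 17.2 ± 2.85 CPM (adjusted p = 0.111), and Ighm, the unswitched isotype, at 9833 ± 1285 and 9730 ± 840 CPM (0.02, adjusted p = 0.963). Cxcl10, an interferon-induced ligand of Cxcr3 that overlaps Art3, changed by -2.52 (SE 0.23). The constant regions are similar in sequence, so reads can be split between them. With the Y-linked level as a covariate, Ighg2c changed by -0.39 (SE 0.73), Ighg3 by 0.26 (SE 0.75) and Ighg1 by 3.33 (SE 1.23), and none of the 3 passed the test. That level moved with the group, so this fit cannot separate them. No test here ties the isotypes to Tbx21.

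In the shTet2 lymphoma cells 2 constant region genes passed the test. Ighm rose to 3902 ± 115 CPM (SD, n = 2) from 2395 ± 260 CPM (SD, n = 5), a log2 change of 0.70 (adjusted p = 0.0101), and Ighe, the IgE constant region, rose to 7.02 ± 0.410 from 0.911 ± 0.521 CPM (2.95, SE 0.34, adjusted p = 0.00317). Ighg1 (1.96, SE 1.20), Ighg2c (1.13, SE 0.85) and Ighg3 (0.49, SE 0.51) did not pass the test. The difference between the 2 effects, GC B-cell minus lymphoma, passed for Ighg2c (-4.80, SE 0.93, adjusted p = 0.0163), Ighe (-2.93, SE 0.60, adjusted p = 0.0163) and Ighm (-0.66, SE 0.18, adjusted p = 0.0358), but not for Ighg1 (1.02, SE 1.15, adjusted p = 0.680) or Ighg3 (-1.56, SE 0.56, adjusted p = 0.153).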
